A study of Mus musculus with 2 samples.

How the data were processed

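Single bone marrow cells of mice labelled Ogfrl1 +/+ and Ogfrl1 -/- were captured with a droplet kit for 3' ends, with 1 library per genotype. The deposited counts were UMI counts per gene and barcode, which the authors made with Cell Ranger 5.0.1, STAR and mm10, per the submitters' processing notes. The annotation the authors counted against was not given in the sources used here. The values were whole counts, and no normalization had been applied to them. Gene positions came from GENCODE release M21 on GRCm38, which is mm10, joined by gene ID.

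Cells with under 200 genes or with over 10% mitochondrial UMIs were left out, 41 and 109 barcodes in the library labelled WT and 29 and 21 in the library labelled KO. Doublets were called per library with Scrublet at an expected rate of 7% and left out, 337 cells (3.78%) and 235 cells (2.82%). The cells kept numbered 8582 and 8111, with medians of 4706 and 5436 UMIs and 1269 and 1387 genes. Their median mitochondrial share was 1.66% and 1.599%.

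Counts were scaled to 10000 UMIs per cell and log-transformed, and both libraries were clustered together without batch correction. The clustering used 2000 variable genes, 30 components, 15 neighbours and Leiden resolution 1, with seed 1. Ogfrl1, sex-check, mitochondrial, ribosomal and haemoglobin genes and immunoglobulin and T cell receptor segment genes were kept out of the variable genes. Each of the 28 clusters was named by the best of 20 marker sets fixed before the data were examined. A name needed at least 3 markers detected in at least 10% of the cells, and a score above 0. Where the cluster's top 10 genes held markers of another class, they had to hold more of the named class, or as many with a lead of at least 1 in score. This rule for ties was set after the data had been seen, and 1 cluster stayed unnamed. The immature neutrophil class joined clusters 5, 8 and 12, mature neutrophils 6 and 7, and monocytes 3, 10, 19, 25 and 27. Immature or mature B cells joined clusters 1, 4 and 28, and pro-B or pre-B cells 2, 13, 17 and 20. Granulocyte-monocyte progenitors or promyelocytes joined clusters 11 and 18, and basophils or mast cells 21 and 26. The other classes were single clusters.

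UMIs were summed per gene and library over all cells and within each of the 10 classes with at least 100 cells in each library. Levels were given as CPM with exact Poisson intervals, ratios with exact conditional binomial intervals, and shares with exact Clopper-Pearson intervals, each at the 95% level. These intervals cover counting error only, and with 1 library per genotype no test between genotypes was run. Genes were named by a fixed rule: at least 100 UMIs over both libraries, at least 30 CPM in a library, and the 6 per direction whose interval lay furthest from 0. This was done over all cells and in the 4 largest classes. Genes with a ratio of at least 1.5 in the same direction in at least 3 classes were gathered across classes, and up to 10 per direction were named. Predicted genes (Gm and Rik names), immunoglobulin and T cell receptor segments, mitochondrial, ribosomal protein and haemoglobin genes and sex-check genes were left out of naming by rank, by a rule fixed before the data were examined.

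The 27 gene lists were fixed before the data were examined. A member needed at least 20 UMIs over both libraries, and 0.5 UMIs were added to each sum for the list medians. Each median was placed among 10000 random lists of equal size drawn from 20 expression bins, as a description of these libraries. Cycling cells were counted after thinning each cell to 1000 UMIs at random, which left out 321 and 96 cells that were too shallow. The 3' ends of transcripts, the last 300 bases, were compared with all transcripts by BLAST 2.17.0. A match to another gene of at least 95% identity over at least 80 bases was taken as a near-identical copy.

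The alternatives tried were no cell filter, a stricter filter (500 genes, 5% mitochondrial UMIs), doublet calls kept, Leiden resolutions 0.5 and 2, and each library clustered on its own. Further ones were a clustering without 448 genes that differed across classes, thinning, other minimum counts for list members and cycling cells, edgeR TMM scaling and DESeq2 median of ratios scaling. The R packages were used for these scalings and for nothing else. After the data had been seen, 3 more were added. They were plasma cells defined by immunoglobulin and Jchain, 186 and 193 mixed cells left out for holding at least 1% of UMIs from S100a8, S100a9, Ngp, Camp and Ltf, and immature neutrophils without cluster 8.

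The steps were tested on simulated Poisson counts drawn from a pooled profile. These held no variation between cells or libraries, so the coverage below speaks for counting error only. Among 12305 genes, 67 were planted with a 1.5-fold, 67 with a 2-fold and 66 with a 4-fold difference, leaving out the genes with the largest shares of UMIs. Of these 94.0%, 98.5% and 100% were recovered, by an interval on the planted side of 0. Of the intervals of all genes measured, 95.5% covered the true ratio. With fewer UMIs, as in a class, and 8346 genes, 80.6%, 97.0% and 100% were recovered, with a coverage of 95.3%. A list planted at 0.8-fold, a log2 ratio of -0.322, came out at -0.326 and -0.314. An unchanged list came out at percentiles 89.0 and 72.3 of random lists. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.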

Results

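Bone marrow cells labelled as those of Ogfrl1-deficient mice and of littermate controls were profiled with a droplet kit that counts the 3' ends of transcripts with unique molecular identifiers (UMIs). The cells came from femur and tibia, and red cells had been lysed. There was 1 library per genotype, labelled WT (Ogfrl1 +/+) and KO (Ogfrl1 -/-). Nothing in the labels says how many animals went into a library, so every comparison sets 1 library against 1 other library. The library labelled WT held 9052 barcodes with 71397254 UMIs, a median of 4824 per barcode. The library labelled KO held 8387 barcodes with 83607727 UMIs, a median of 5566. After the filters on cells, 8582 and 8111 cells remained, with 67034663 and 80528707 UMIs. Intervals are exact 95% intervals and cover counting error only. They do not cover differences between animals or preparations, and no test or p-value was computed. For summed UMIs they take each UMI as independent and do not cover differences between cells. Where a few cells hold most UMIs of a gene, they are too narrow. Ratios are given as log2 of the level in the library labelled KO over that in the library labelled WT. Class names stand for clusters that resemble a cell type by markers fixed before the data were examined.

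The comparison asks how marrow cells differ in the absence of Ogfrl1, the opioid growth factor receptor-like 1 gene, so its own level was taken first. Over all cells Ogfrl1 was level, with 7633 UMIs in the library labelled WT and 9099 in the library labelled KO. In the usual CPM unit, UMIs scaled to the summed UMIs of the cells considered, this made 114 CPM (interval 111 to 117) and 113 CPM (111 to 115), a log2 ratio of -0.01 (-0.06 to 0.03), which moved to -0.20 when each cell was thinned to 1000 UMIs. In immature neutrophils, the class with most Ogfrl1 UMIs, both libraries held 179.6 CPM, with intervals of 173 to 186 and 174 to 185, a log2 ratio of 0.00 that came to -0.18 after TMM scaling. Mature neutrophils held 289.7 and 267 CPM, and monocytes 112 and 102 CPM. Erythroid cells held more in the library labelled KO, at 78.0 and 97.6 CPM. Ogfrl1 (ENSMUSG00000026158) lies on the minus strand of chromosome 1 of GRCm38, from 23366424 to 23397772. Its transcript Ogfrl1-201 has 7 exons, and the last one, where 3' tags of this transcript would fall, spans 23366424 to 23370448. That of Ogfrl1-204 lies elsewhere, at 23391749 to 23393011, and the counts hold no positions. The labels do not state which part was deleted, and a 3' tag outside the deleted part is no check of the genotype. Since Ogfrl1 was not lower over all cells, directions are given between the libraries as labelled, and the counts do not exclude an exchange or a mix of the libraries.

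In lymphoid cells Ogfrl1 was lower in the library labelled KO. Immature or mature B cells held 23.4 CPM (142 UMIs) in the library labelled WT and 6.44 CPM (40 UMIs) in the library labelled KO, a log2 ratio of -1.86 (-2.40 to -1.34). Pro-B or pre-B cells held 43.0 and 19.0 CPM, from 305 and 154 UMIs, a log2 ratio of -1.18 (-1.46 to -0.89). The largest gap with over 100 UMIs was in cluster 2, pre-B cells led by Rag1 and Il2ra, with 56.2 and 7.03 CPM, 7.99-fold lower in the library labelled KO. Clusters 1 and 4 of the immature or mature B cells were 3.37-fold and 3.86-fold lower, and cluster 28 held 9 and 4 UMIs. Clusters 13 and 17 of the pro-B or pre-B cells were 1.61-fold and 1.55-fold lower, and cluster 20 was the exception at a log2 ratio of 0.14 (-0.62 to 0.92). T cells held 15 UMIs against 1, a log2 ratio of -4.32 (-9.72 to -1.62), which came to -0.81 with doublet calls kept. Natural killer cells held 1 and 3 UMIs, too few for a direction. Plasma cell cluster 24 held 15 and 2 UMIs, at 33.8 and 3.81 CPM, but did not hold the same kind of cell in the libraries. Beyond the lymphoid clusters, monocyte cluster 27 held 204 and 96.3 CPM from 22 UMIs in each library. The name of cluster 2 was close, with a score of 0.508 against 0.450 for immature or mature B cells. At Leiden resolution 0.5 the matching cluster of 2007 cells stayed unnamed, and the pro-B or pre-B log2 ratio without it was -0.55. At resolution 2 it was -0.80.

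**Figure D1:**
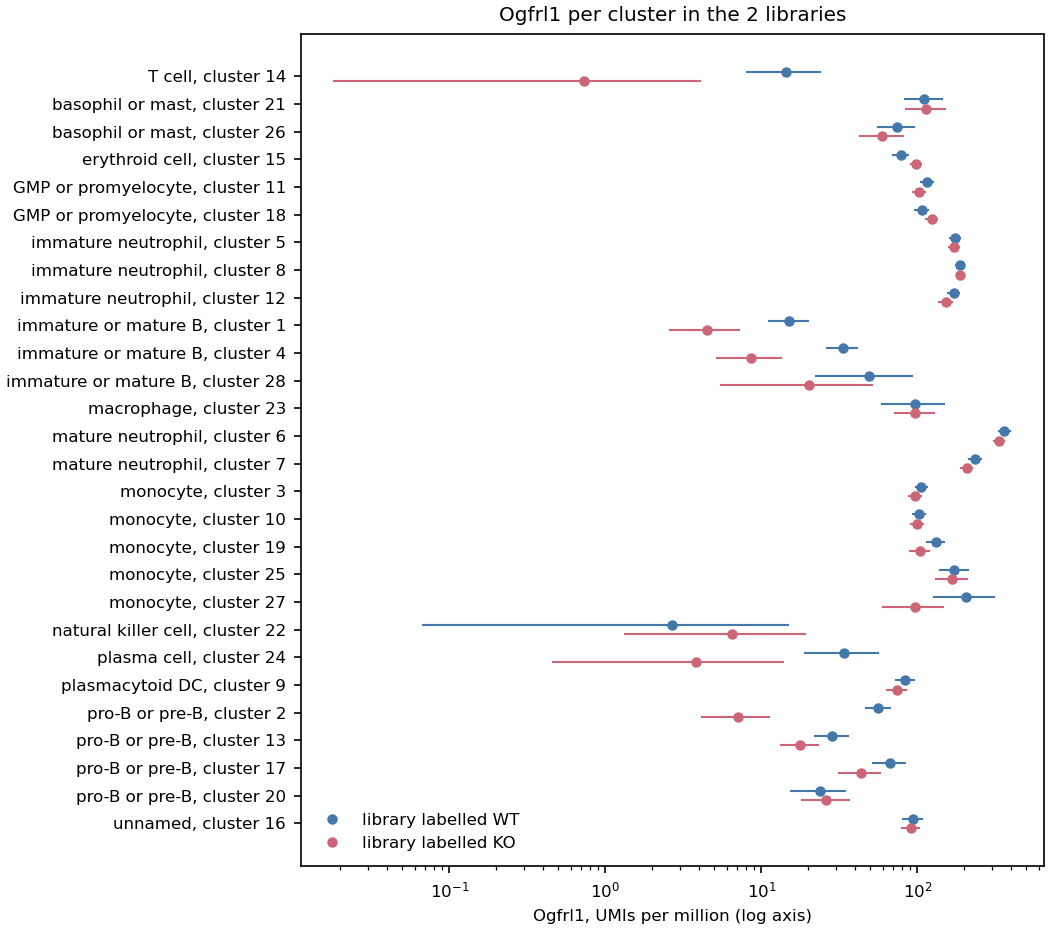
Ogfrl1 level in CPM (log axis) in each cluster, with the library labelled WT in blue and the library labelled KO in red; points are levels from summed UMIs and lines are exact Poisson 95% intervals for counting error. Immature neutrophil clusters overlap at 152 to 187 CPM, while pre-B cluster 2 sits at 56.2 and 7.03.

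Most classes held similar shares of cells in both libraries. B lineage cells made 39.6% of the library labelled WT and 40.2% of the library labelled KO. Monocytes were fewer in the library labelled KO, at 15.6% (14.8 to 16.3) against 12.8% (12.1 to 13.6), a share ratio of 0.824 (0.759 to 0.894). Mature neutrophils were more frequent there, at 10.8% (10.1 to 11.5) against 12.97% (12.3 to 13.7), a share ratio of 1.20 (1.098 to 1.31). T cells made 2.19% and 2.85%, a share ratio of 1.30 (1.07 to 1.59). Erythroid cells made 2.04% and 2.82%, a share ratio of 1.39 (1.13 to 1.695), and red cell lysis can set this share. Over every barcode the erythroid log2 share ratio turned to -0.06. Plasmacytoid dendritic cells made 3.94% and 3.34%, a share ratio of 0.848 (0.720 to 0.998). The neutrophil lineage as a whole made 25.3% and 27.3%, and its direction turned under a stricter cell filter. For the remaining classes the ratio interval held 1. These were immature neutrophils (14.5% and 14.3%), immature or mature B cells (23.6% and 23.4%), pro-B or pre-B cells (16.0% and 16.9%), and granulocyte-monocyte progenitors or promyelocytes (4.85% and 4.61%). They also included basophils or mast cells (1.78% and 1.62%), natural killer cells (0.816% and 0.974%) and macrophages (0.874% and 0.900%). Cluster 16 joined megakaryocyte genes (Pf4, Gp1bb) with progenitor genes (Hlf, Adgrl4), stayed unnamed, and held 1.86% and 2.21% of cells.

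The plasma cell cluster did not hold the same kind of cell in the libraries. It held 105 cells with a median of 1360 UMIs in the library labelled WT and 31 cells with a median of 18249 UMIs in the library labelled KO. At least 3 plasma cell markers were seen in 15.2% and 74.2% of these cells, and the median share of immunoglobulin UMIs was 0.0347% and 23.7%. Cells with at least 5% immunoglobulin UMIs and 5 UMIs of Jchain, the joining chain of secreted antibody, numbered 23 (0.268%) and 31 (0.382%), a share ratio of 1.43 (0.805 to 2.56). This second definition was chosen after the cluster had been seen. No direction is therefore drawn from the cluster's own shares of 1.22% and 0.382%.

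**Figure D2:**
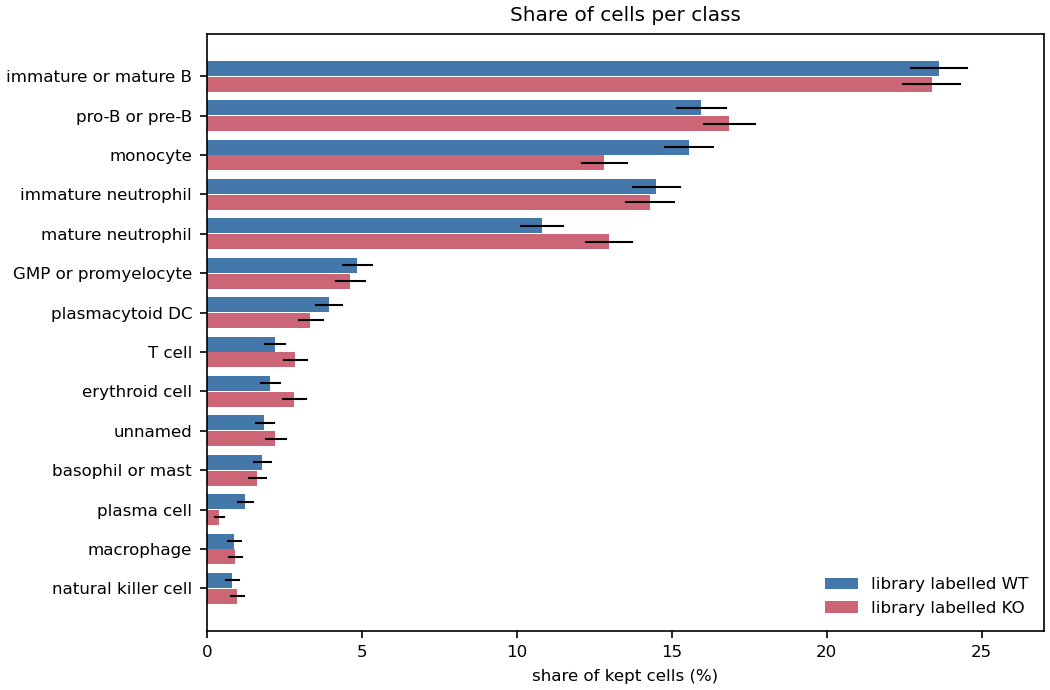
Share of kept cells per class in percent, with the library labelled WT in blue and the library labelled KO in red; bars are shares from 0 and lines are exact binomial 95% intervals for counting error. Monocytes stand at 15.6% and 12.8% and mature neutrophils at 10.8% and 12.97%, and the plasma cell bars count a cluster that mixes cell kinds in the library labelled WT.

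Over all cells the summed profiles were close, with a Pearson correlation across genes of 0.996 on the log scale, where genes are not independent replicates. Genes open to naming leave out predicted, immunoglobulin, ribosomal protein and mitochondrial genes. Among those with at least 30 CPM in a library, the histone gene Hist1h2ap had the interval furthest from 0, at 1312 and 349.8 CPM, 3.75-fold lower in the library labelled KO. Genes below that level could stand further apart, such as Slc15a2 with 147 and 20 UMIs. Hist1h2ap (ENSMUSG00000094777) lies on chromosome 13 of GRCm38, from 21833026 to 21833507. Lower there were also Gzma (granzyme A of cytotoxic lymphocytes), 1.79-fold, the AP-1 factor Fosb, 1.67-fold, and the RNA polymerase subunit gene Polr2l, 1.60-fold. The basophil protease Mcpt8 was 1.42-fold lower and the glycolytic enzyme gene Eno1 1.37-fold lower. Higher in the library labelled KO were Usp50 at 18.5 and 43.3 CPM (2.34-fold), Nutf2-ps1 (2.19-fold), the small nucleolar RNA host gene Snhg9 (2.18-fold), and Ftl1-ps1 (2.06-fold). Usp50 (ENSMUSG00000027364) lies on chromosome 2, from 126709096 to 126783470, and Snhg9 (ENSMUSG00000090101) on chromosome 17, from 24719531 to 24719965. Phpt1 was 1.72-fold and the histone gene Hist1h2ag 1.69-fold higher. All 12 kept their direction under each alternative tried. Part or all of the 3' end of some of these genes matched a transcript of another gene, taken as a near-identical copy. Usp50, Nutf2-ps1, Ftl1-ps1, Phpt1, Hist1h2ag, Hist1h2ap, Polr2l and Eno1 have such a copy, so their own levels are uncertain. The processing notes name the same build and software for both libraries, but read length and annotation were not given, and a difference in either between the libraries would change these ratios.

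Genes induced by type I interferon were lower in the library labelled KO. All 24 measured members of the list had a log2 ratio below 0 over all cells, with a median of -0.26, below each of 10000 random lists matched on expression (percentile 0, as a description of these libraries). Ifi27l2a stood at 586 and 447 CPM, 1.31-fold lower, and Ifitm3, which blocks virus entry, at 747 and 628. The antiviral ubiquitin-like gene Isg15 stood at 26.96 and 21.7 CPM and the transcription factor Irf7 at 26.0 and 20.3. Genes of MHC class I presentation went the same way, with 10 of 11 below 0 and a median of -0.14 (percentile 0.0100). The peptide transporter Tap1 had a log2 ratio of -0.37 and H2-K1 of -0.17, and the exception was the proteasome gene Psmb8 at 0.02. MHC class II presentation was mixed, with 6 of 10 below 0 and a median of -0.09 (percentile 0.270). Its transactivator Ciita had a log2 ratio of -0.35 and H2-Eb1 of 0.19, and the list's median turned to 0.16 after thinning.

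Within classes the interferon list was lower in the library labelled KO in 9 of 10 classes. Its median was -0.32 in monocytes, -0.33 in immature or mature B cells, -0.33 in pro-B or pre-B cells and -0.34 in plasmacytoid dendritic cells, which are a main source of type I interferon. It was -0.36 in mature neutrophils, -0.42 in granulocyte-monocyte progenitors or promyelocytes and -0.50 in T cells. The T cell median turned to 0.15 after thinning, and the progenitor median to 0.01 at Leiden resolution 2. Other lists went along in some classes, with ribosomal protein genes at -0.36 (79 of 82 below 0) and mitochondrial genes at 0.33 in mature neutrophils. Monocyte and macrophage genes stood at -0.78 in T cells (9 of 9 below 0) and -0.58 in immature or mature B cells. Neutrophil lists were higher in plasmacytoid dendritic cells, at 2.37 for secondary granules (13 of 13 above 0), 1.59 for mature neutrophil genes and 2.05 for alarmins. In pro-B or pre-B cells secondary granules stood at 1.37 (12 of 12 above 0). With mixed cells left out, who were picked in part by genes of that list, these secondary granule medians turned to -0.11 and -0.14. At Leiden resolution 2 that of plasmacytoid dendritic cells turned to -0.13. The interferon median was nearer 0 in erythroid cells (-0.10) and in basophils or mast cells (-0.13). The erythroid median turned to 0.15 after thinning and to 0.29 with mixed cells left out, which left 8 of 10 classes below 0. In monocytes 22 of 24 members were below 0, with Isg15 at 54.0 and 40.5 CPM, and Ifit3 and Cmpk2 near 0 at log2 ratios of 0.04 and 0.01. In plasmacytoid dendritic cells Irf7 stood at 104 and 65.2 CPM, a log2 ratio of -0.67 (-0.95 to -0.40). Immature neutrophils were the exception, with a median of 0.47, or 0.29 after TMM scaling, and genes of monocytes, B cells and stroma were higher in that class too. That median came to -0.17 without cluster 8, an alternative chosen after the data had been seen. Among single clusters 23 of the 27 measured had a median below 0. The others were cluster 8, plasma cell cluster 24 (0.51), the unnamed cluster 16 (0.02) and cluster 25 (0.06), monocytes led by Cxcl10 and Ifit3. After thinning, 6 of the 9 classes measured were below 0, and the others were T cells, erythroid cells and immature neutrophils, the last of which had been above 0 before.

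**Figure D3:**
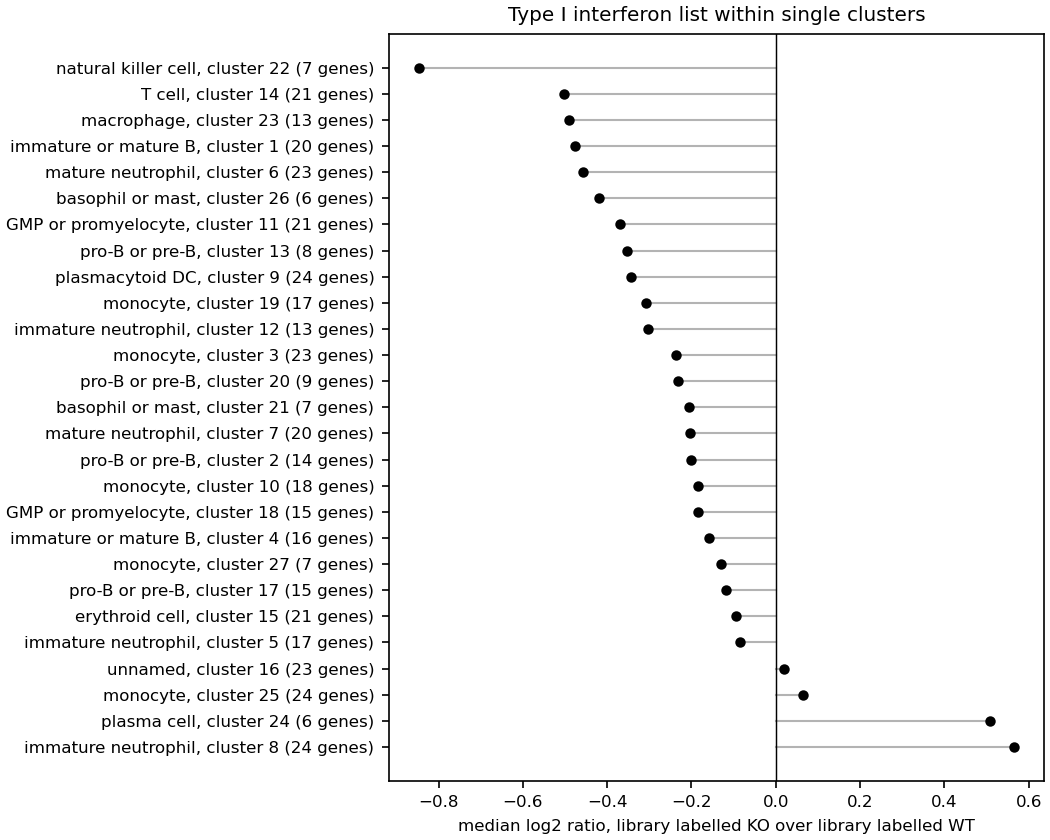
Median log2 ratio (library labelled KO over library labelled WT) of the measured type I interferon genes within each cluster; each point is 1 cluster, with its number of measured genes in brackets. Of 27 clusters 23 lie left of 0, and immature neutrophil cluster 8 lies furthest right at 0.57.

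Neutrophil genes were higher over all cells in the library labelled KO, which also held more mature neutrophils. Of 18 mature neutrophil and gelatinase granule genes 17 were above 0, with a median of 0.32 (percentile 100) and the exception Wfdc17 at -0.07. The chemokine receptor gene Cxcr2 stood at 84.0 and 115 CPM and the cytokine gene Il1b at 19.5 and 29.5. Within the mature neutrophil class the list's median was 0.08, so little of the gap remained there. Primary granule genes had 8 of 9 above 0 and a median of 0.25 (percentile 100), which turned to -0.00 after thinning. The proteases Elane and Prtn3 had log2 ratios of 0.37 and 0.25 and Ctsc was the exception at -0.27. Secondary granule genes had 9 of 13 above 0 and a median of 0.06 (percentile 76.0), with Camp at 0.06 and Ltf at 0.12. Within immature neutrophils, which make these granules, 12 of 13 were below 0, with a median of -0.17, or -0.35 after TMM scaling. Primary granule genes were at 0.50 in immature neutrophils (9 of 9 above 0), or 0.32 after TMM scaling, 0.20 in granulocyte-monocyte progenitors or promyelocytes (8 of 9) and 0.26 in monocytes (7 of 9), and at -1.02 in mature neutrophils, with 7 of 9 below 0. Immature neutrophil cluster 8 held 316 and 460 cells, and without it the primary granule median in that class turned to -0.35 (2 of 9 above 0) and the secondary granule median came to -0.03, an alternative chosen after the data had been seen. Elsewhere the primary granule median was -0.94 in immature or mature B cells, -0.52 in pro-B or pre-B cells, -0.501 in T cells, -0.33 in plasmacytoid dendritic cells and -0.25 in basophils or mast cells, but 0.32 in erythroid cells, with 9 of 9 above 0. All 5 alarmins were above 0, with a median of 0.21 (percentile 99.7), and S100a8 and S100a9 stood at log2 ratios of 0.21 and 0.29. The 12 probes for free RNA had a median of 0.26 (percentile 100), 11 of them above 0 and Ighm the exception at -0.33. Summed over all cells they also count the cells that express them, so this is no measure of free RNA. The list stood at -0.32 in immature or mature B cells and -0.21 in T cells, but at 0.42 in pro-B or pre-B cells and 0.47 in monocytes. The median share per cell of 5 neutrophil genes was lower in the library labelled KO in each of these classes, such as 0.0683% and 0.0362% in monocytes.

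Haemoglobin and haem synthesis genes were higher in the library labelled KO, which held more erythroid cells. All 15 were above 0 over all cells, with a median of 0.45 (percentile 100). The globin gene Hbb-bs stood at 629.5 and 1271 CPM, and Alas2, the first enzyme of haem synthesis in erythroid cells, at a log2 ratio of 1.35. Within the erythroid class 14 of 15 were above 0, with a median of 0.45. Other lists differed in that class too, with medians of 0.84 for mature neutrophil genes (16 of 16 above 0), 0.45 for monocyte and macrophage genes and -0.17 for ribosomal protein genes (75 of 81 below 0). Cells with at least 1% of UMIs from 5 neutrophil genes made 16.6% and 25.3% of it. The haemoglobin list was at 0.598 in immature neutrophils (15 of 15 above 0), -0.41 in T cells and -0.21 in pro-B or pre-B cells. The 11 measured markers of non-haematopoietic cells were all above 0, with a median of 0.59 (percentile 100). Cxcl12, the stromal chemokine, held 261 and 816 UMIs, of which 56 and 650 lay in the immature neutrophil class. Sparc, a matrix protein gene, held 46 and 214, of which 12 and 164 lay in immature neutrophil cluster 8, with 12 and 151 of these in 10 cells per library. Of 14 genes of marrow retention, homing and adhesion 12 were above 0, with a median of 0.08 (percentile 95.6), and Vcam1 stood at a log2 ratio of 0.49.

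Genes of B cell development were lower over all cells in the library labelled KO, with 17 of 22 below 0 and a median of -0.11 (percentile 0). Ighm had a log2 ratio of -0.33, Cd22 of -0.35 and Pax5, the B lineage factor, of -0.29, while Il7r was at 0.11. The list's median was 0.01 within immature or mature B cells and -0.00 within pro-B or pre-B cells, and 0.04 over all cells after thinning. Monocyte and macrophage genes were split, with 10 of 19 below 0 and a median of -0.02 (percentile 9.45). Fn1 and Ms4a6c, genes of classical monocytes, had log2 ratios of -0.39 and -0.34, and the complement genes C1qa and C1qc of macrophages 0.36 and 0.37. Macrophages made 0.874% and 0.900% of cells but held medians of 1202 and 3573 UMIs per cell, and deeper cells weigh more in summed UMIs. In immature neutrophil cluster 8, C1qa held 287 and 647 UMIs.

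Lists tied to Ogfrl1 and to osteoclasts had small medians over all cells, and some differed between classes. The Ogfr family list had a median of -0.01 (percentile 34.2, 2 of 3 below 0), with Ogfr, the opioid growth factor receptor, at 23.4 and 22.4 CPM and Penk, its ligand precursor, at 49 and 78 UMIs. The 7 measured neighbours of Ogfrl1 had a median of -0.08 (percentile 6, 4 below 0), with Smap1 at 0.01 and Phf3 at -0.08. Of 19 osteoclast differentiation genes 11 were below 0, with a median of -0.06 (percentile 1.69). Csf1r, the receptor for macrophage growth factor, stood at -0.08, Nfatc1, the osteoclast master factor, at -0.10 and Acp5 at 0.26. The list's median was 0.53 in erythroid cells, 0.30 in immature neutrophils, -0.201 in immature or mature B cells and -0.21 in granulocyte-monocyte progenitors or promyelocytes. It was near level in monocytes, at 0.02 (10 of 17 above 0), and in mature neutrophils, at 0.01. The Sh3bp2 and Syk signalling list had a median of -0.00 (percentile 25.4, 8 of 16 below 0), with Sh3bp2 at 0.08 and Syk at -0.01. The Toll-like receptor and NF-kB list had a median of -0.00 (percentile 35.1, 12 of 24 below 0). Within it Il1b and Cxcl2 were higher in the library labelled KO, at log2 ratios of 0.60 and 0.48, and Ccl2 and Cxcl10 lower, at -0.67 and -0.45. By class this list was above 0 for 23 of 23 genes in immature neutrophils (median 0.32, against 0.15 for all genes of the class), at 0.56 in erythroid cells, and below 0 for 18 of 20 genes in granulocyte-monocyte progenitors or promyelocytes (-0.33) and 12 of 14 in T cells (-0.36). In monocytes and mature neutrophils its median was near level, at -0.035 and 0.026. Monocyte and macrophage genes went the same way as these 2 lists, with medians of 0.45 in erythroid cells, -0.78 in T cells, -0.58 in immature or mature B cells and -0.26 in the progenitors, and mature neutrophil genes stood at 0.84 in erythroid cells.

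Lists for cell state had small medians over all cells and larger ones in some classes. S phase genes had a median of 0.10 (percentile 99.9, 20 of 25 above 0), led by the helicase subunit gene Mcm7 at 0.53, and G2/M genes 0.07 (percentile 97.7, 21 of 25 above 0), with Top2a at 0.20. G2/M genes stood at 0.95 in T cells, where cycling cells, counted by the same list after thinning, made 18.9% and 12.6%, a log2 share ratio of -0.58 (-1.35 to 0.18). They stood at 0.56 in plasmacytoid dendritic cells, with S phase genes at -0.38 and cycling cells at 16.6% and 16.3%, and 2.96% and 14.8% of these cells had at least 1% of UMIs from the 5 neutrophil genes. Glycolysis and hypoxia genes had a median of 0.10 (percentile 99.2, 12 of 17 above 0), with Ldha at 0.17 and Eno1 at -0.45. Heat shock and unfolded protein genes had a median of 0.10 (percentile 98.7, 13 of 15 above 0), with Hspa8 at 0.17. Immediate early and dissociation stress genes had a median of 0.02 (percentile 47.9, 9 of 17 above 0), with Fosb at -0.74, Jun at -0.27 and Dusp1 at 0.27. Oxidative phosphorylation genes had a median of 0.04 (percentile 87.2, 66 of 90 above 0), with Ndufa12 at 0.19. Ribosomal protein genes had a median of 0.01 (percentile 1.55, 48 of 83 above 0). Mitochondrially encoded genes had a median of -0.09 (percentile 0.0300, 11 of 13 below 0), with mt-Co1 at -0.29. The sex check list had a median of 0.19 (percentile 98.6, 4 of 5 above 0), and Ddx3y, on the Y chromosome, held 1542 and 2115 UMIs, so both libraries held cells from males.

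In immature or mature B cells the genes named by the same rule fell into 2 sets. Among those higher in the library labelled KO were Snhg9 at 14.97 and 36.0 CPM (2.41-fold), Usp50 (2.38-fold), Wdr89 (1.72-fold), Fam32a (1.61-fold) and the chaperone gene Dnaja1 (1.57-fold). Lower were Hist1h2ap (3.61-fold) and 5 genes of neutrophils and their precursors. These were Prtn3 (3.40-fold), S100a8 at 814 and 276 CPM (2.95-fold), S100a9 (2.41-fold), Camp (1.78-fold) and the lysozyme gene Lyz2 (1.69-fold). B cells should lack S100a8, and 84.4% and 55.3% of them held an S100a8 UMI, at median depths of 2823 and 2926 UMIs per cell. T cells, which should lack it too, showed 86.7% and 58.0% at median depths of 5354 and 5527. Heat shock and unfolded protein genes had a median of 0.28 in this class, 12 of 15 above 0. Usp50, Lyz2 and Hist1h2ap have near-identical copies and uncertain levels.

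In pro-B or pre-B cells Ogfrl1 was among the 6 genes named as lower in the library labelled KO. The others were Hist1h2ap (3.19-fold), the AP-1 genes Fosb (1.83-fold) and Fos (1.73-fold), the transcription factor Klf4 (1.74-fold) and Polr2l (1.63-fold). The 6 named as higher were all neutrophil genes, with Chil3 3.81-fold, Camp 3.44-fold, Ngp 3.32-fold, Lcn2 2.84-fold, S100a9 2.79-fold and S100a8 2.49-fold higher. Cells with at least 1% of their UMIs from S100a8, S100a9, Ngp, Camp and Ltf numbered 20 of 1369 and 19 of 1367, and those with at least 5% numbered 4 and 10. The median share of these 5 genes per cell went the other way, at 0.139% in the library labelled WT and 0.0591% in the library labelled KO. With the cells at or above 1% left out as mixed cells, an alternative chosen after the data had been seen, the log2 ratio was -0.70 for Camp, -0.03 for Ngp, -0.98 for S100a9 and -1.19 for S100a8. The mixed cells were picked by these same genes, so part of this turn follows from the choice. Hist1h2ap and Polr2l have near-identical copies.

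The 3 immature neutrophil clusters made up different parts of the class in the libraries. Cluster 8 held 316 and 460 cells, with medians of 17174 and 22060 UMIs per cell, cluster 5 held 650 and 494, and cluster 12 held 278 and 205. All genes of the class had a median log2 ratio of 0.15, and TMM scaling lowered each ratio there by 0.175. After TMM scaling, Cxcl12 stood at 2.88, Cstdc4, a cysteine protease inhibitor gene, at 2.74, the chemokine Ccl6 at 1.68 and F13a1, the A chain of clotting factor XIII, at 1.42. S100a10 stood at 1.30 and Crip1 at 1.22. Genes of other cell types were higher alongside, with unscaled medians of 1.097 for monocyte and macrophage genes (19 of 19 above 0), 0.98 for MHC class II, 0.70 for B cell development (20 of 20) and 1.84 for non-haematopoietic markers. In cluster 8, 10 cells carried 522 of the 638 Cxcl12 UMIs of the library labelled KO. Without cluster 8 the unscaled log2 ratios turned to -0.26 for Cxcl12, -0.03 for Crip1 and -0.53 for S100a10. Lower after TMM scaling were Hist1h2ap (-2.24), the mitochondrial leucyl-tRNA synthetase gene Lars2 (-0.70), Eno1 (-0.70), Thbs1 (-0.70), Hist1h2br (-0.67) and AY036118 (-0.52). With across-class genes out of the clustering F13a1 turned to -0.31 and Thbs1 to 0.04. Hist1h2ap, Hist1h2br, Eno1 and AY036118 have near-identical copies.

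In monocytes the neutrophil genes Retnlg (2.71-fold) and Ltf (1.88-fold) were higher in the library labelled KO, with Usp50 (2.34-fold), Nutf2-ps1 (2.30-fold), Ftl1-ps1 (1.91-fold) and Hist1h2ag (1.89-fold). With mixed cells left out the log2 ratio of Retnlg turned to -0.66. Lower there were Hist1h2ap (3.38-fold), Arhgap31, a GTPase activator gene, at 40.3 and 24.6 CPM (1.64-fold), Polr2l (1.60-fold) and the monocyte chemoattractant gene Ccl2 at 33.6 and 21.7 CPM (1.55-fold). Fosb was 1.55-fold and Dleu2 1.44-fold lower. Of 17 immediate early genes 13 were below 0, with a median of -0.17, and all 11 MHC class I genes were below 0, with a median of -0.19. G2/M genes had 24 of 25 above 0 and a median of 0.21, while cycling cells made 46.3% and 48.99% of the class, a log2 share ratio of 0.08 (-0.09 to 0.25). The class was made up differently, with 817 of 1335 and 573 of 1039 cells in cluster 3, 293 and 263 in cluster 10, led in part by histone genes, and 130 and 109 in cluster 19, led in part by mitotic genes. Usp50, Nutf2-ps1, Ftl1-ps1, Hist1h2ag, Hist1h2ap, Polr2l and Dleu2 have near-identical copies.

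Across the 10 classes with at least 100 cells per library, 100 genes were at least 1.5-fold higher in the library labelled KO in at least 3 classes and 17 at least 1.5-fold lower, with log2 intervals on that side of 0 and no class with an interval on the other side. Among the genes open to naming the highest by median log2 ratio were Ly6k (2.98, in 5 of 5 classes measured), Cstdc4 (2.92, 4 of 5), the X-linked Xlr3b (1.92, 4 of 5), Stfa2l1 (1.61, 4 of 5) and Eno1b (1.60, 8 of 9). Next came Il1b (1.55, 3 of 5), P3h3 (1.52, 3 of 4), the short noncoding RNA gene Bc1 (1.38, 7 of 10), Il2 (1.30, 3 of 6) and Hmga1b (1.29, 5 of 7). In mature neutrophils Cstdc4 stood at -0.04, Stfa2l1 at 0.21 and Il1b at 0.03, so these neutrophil genes were level or nearly so in the class that holds most of their UMIs. Cells with at least 1% of UMIs from 5 neutrophil genes made 2.96% and 14.8% of plasmacytoid dendritic cells and 16.6% and 25.3% of erythroid cells. The lowest open to naming were Slc15a2, a peptide transporter gene (-4.17, in 3 of 3, a median over the 2 with UMIs in both libraries), Hist1h2ap (-1.83, 9 of 10), Xlr (-1.60, 3 of 4), Mtus2 (-1.30, 3 of 7) and the glutathione transferase gene Gstp1 (-1.23, 9 of 9). Then came Polr2l (-0.80, 7 of 10), Pitrm1 (-0.78, 4 of 8), Psme2b (-0.67, 4 of 8), Plk2 (-0.67, 3 of 6) and Fosb (-0.63, 6 of 10). Xlr3b, Stfa2l1, Eno1b, Bc1, Il2, Hmga1b, Hist1h2ap, Gstp1, Polr2l and Psme2b have near-identical copies and uncertain levels.

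Cycling cells were taken as those with at least 2 UMIs from the G2/M list after thinning each cell to 1000 UMIs. They made 38.0% (37.0 to 39.1) of 8261 cells in the library labelled WT and 36.5% (35.4 to 37.5) of 8015 in the library labelled KO, a log2 share ratio of -0.06 (-0.13 to 0.01). Unthinned, the shares were 74.2% and 72.0%. The list holds Hmgb2, which many cells express, and mature neutrophils, which do not divide, reached 42.4% and 38.8%, so the shares are no count of dividing cells. Immature or mature B cells stood at 10.4% (9.07 to 11.9) and 7.24% (6.11 to 8.50), a log2 share ratio of -0.52 (-0.85 to -0.20). The G2/M list itself was near level in that class, with a median of -0.03 and 11 of 25 genes above 0. Pro-B or pre-B cells stood at 37.1% and 36.9%.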

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

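Values are log2 ratios, library labelled KO over library labelled WT, and causes were not tested unless stated. No paired analysis was possible because there was 1 library per genotype and no label links their cells or animals. Over every barcode the erythroid share turned to -0.055 and the plasma cell share to 0.737. Under the stricter cell filter the plasma cell share turned to 0.420 and the neutrophil lineage share to -0.071. By immunoglobulin and Jchain the plasma cell share was 0.512, because the plasma cell cluster of the library labelled WT held mostly other cells.

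Ogfrl1 in pro-B or pre-B cells moved to -0.550 at Leiden resolution 0.5, -0.797 at resolution 2, -0.557 with the libraries clustered separately and -0.548 with across-class genes out of the clustering. At resolution 2 the interferon median in granulocyte-monocyte progenitors or promyelocytes turned to 0.006 and the secondary granule median in plasmacytoid dendritic cells to -0.133. With across-class genes out of the clustering, the neutrophil lineage share turned to -0.005, F13a1 in immature neutrophils to -0.308 and Thbs1 there to 0.037.

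With cells thinned to 1000 UMIs, which gives each cell equal weight, Ogfrl1 moved to -0.201 over all cells and to -2.008 in pro-B or pre-B cells. In the latter S100a9 turned to -0.290 and S100a8 to -0.561. List medians turned to 0.155 for MHC class II, -0.001 for primary granules and 0.039 for B cell development over all cells, and for interferon to 0.153 in T cells and 0.154 in erythroid cells. Median of ratios scaling, which moves every gene over all cells alike by -0.013, turned the ribosomal list from 0.009 to -0.004, which leaves its place among other genes as it was.

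With mixed cells left out, pro-B or pre-B cells turned to -0.701 for Camp, -0.034 for Ngp, -0.983 for S100a9 and -1.190 for S100a8, and monocytes to -0.656 for Retnlg. The secondary granule median turned from 1.396 to -0.20 in basophils or mast cells, from 0.191 to -0.037 in monocytes, from 2.367 to -0.113 in plasmacytoid dendritic cells and from 1.374 to -0.138 in pro-B or pre-B cells, and the interferon median in erythroid cells to 0.293. The mixed cells were chosen by S100a8, S100a9, Ngp, Camp and Ltf, so part of the turns of these genes and of the secondary granule list follows from the choice. Without cluster 8 the immature neutrophil class turned to -0.263 for Cxcl12, -0.029 for Crip1, -0.531 for S100a10, -0.173 for the interferon list and -0.347 for primary granules, and 6 of its 12 named genes kept a ratio of at least 1.1 in their direction. Lars2, Hist1h2br and AY036118 kept their sign with a smaller ratio.

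Of 113 alternative Ogfrl1 values 97 stayed within the spread, 94 of 111 class shares, 281 of 316 list medians and 400 of 589 named gene ratios. Where the reported value had a clear direction, by its interval or by its percentile among random lists, the sign changed in 0, 6, 12 and 12 of them. Values near 0 changed sign as well and are not in these numbers, such as Ogfrl1 in immature neutrophils, at -0.175 after TMM scaling.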

Other observations

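The mitochondrial gene mt-Atp8 stood apart from its neighbours. Over all cells it held 286 and 443 CPM, a log2 ratio of 0.63 (0.60 to 0.65), while 11 of the 13 mitochondrially encoded genes were lower in the library labelled KO. It was higher in each of the 10 classes compared, from 0.46 in plasmacytoid dendritic cells to 0.95 in immature neutrophils. The gene mt-Atp6, whose reading frame starts inside that of mt-Atp8 on the same transcript, stood at -0.09 over all cells. Both are read from 1 RNA, so how reads were shared out between them bears on these values, and read positions were not used here.

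Among the genes found across classes, several lie close together on chromosome 16. Stfa2l1 (start 36156811) and Cstdc4 (36184212), which encode cysteine protease inhibitors of neutrophils, were higher in the library labelled KO over all cells and level or nearly so in mature neutrophils, at 0.205 and -0.041. Cstdc5 (36359382) was higher in mature neutrophils too, at 1.213. Slc15a2 (36750177) was lower, with 147 and 20 UMIs over all cells, and so was Arhgap31 (38598340) in monocytes. This was noticed in the results and not tested. Igha, the heavy chain of secreted IgA, held 35 and 1270 UMIs in monocytes and 18334 and 38916 over all cells.

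Ogfrl1 was lower in the lymphoid classes of the library labelled KO and level over all cells, where thinning moved the log2 ratio to -0.201. The tests for this pattern were chosen after the result was seen, and the one for the mix of clusters replaced an earlier one after the values per cluster were seen. Free neutrophil RNA was excluded as the source of Ogfrl1 in B cells of the library labelled WT, since its lower bound there was 16.9 times what that RNA brings, and free RNA of other cells was not estimated. A different mix of the B lineage and T cell clusters cannot alone account for the lower lymphoid level. The ratio within them was -1.363 (-1.609 to -1.118) over 7, those with at least 20 UMIs and the T cells (15 and 1). It was -1.362 (-1.605 to -1.118) over all 8. These pool unlike clusters, from -4.319 in T cells to 0.142 in cluster 20, for which the earlier test was not met. A different mix of cells within a cluster, such as cluster 2, was not tested. A transcript whose 3' end lies outside the deleted part could not be told from an intact gene, since the ratio over all cells was 0.992 (0.962 to 1.02) and the counts hold no positions, so an effect of genotype stays open, as does an exchange or a mix of the libraries.

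For the second pattern, the 117 genes with the same direction in several classes, the tests of shared reads and of depth were chosen before their results were seen and the test of a strain variant after. Reads shared between paralogs or pseudogenes fit part of the pattern, since 48 of these genes, 41.0% (32.0 to 50.5), had a near-identical copy against 6.84% (2.56 to 12) of matched genes. The match does not tell a paralog or pseudogene from another shared stretch of sequence, and Gm3839 matched 133 genes and Csf3r 44. The pairs Eno1 (-0.453) and Eno1b (1.576), Hmga1 (-0.401) and Hmga1b (1.166), and Rpl10 (-0.366) and Rpl10-ps3 (1.079) gave -0.256, -0.063 and -0.287 together, and Hist1h2ap (-1.907) gave -0.423 with the other Hist1h2a genes (0.248). Of these only Hmga1 with Hmga1b offset each other, with an interval of -0.158 to 0.033 for their sum. Nutf2 at -0.039 and Nutf2-ps1 at 1.131 gave 0.898. Ftl1 (0.037) and Rps27 (0.092) were not lower while Ftl1-ps1 (1.040) and Rps27rt (0.927) were higher. Over 94 of these genes in B cells the median absolute log2 ratio was 0.684 after thinning and 0.705 before. This cannot exclude depth, since thinning keeps each gene's expected share of a cell's UMIs. B cells also had close depths before it, with medians of 2823 and 2926 UMIs per cell. A strain variant around Ogfrl1 was excluded as the source of these genes as a set, with 0% within 20 Mb (upper bound 3.1%). Neutrophil RNA in cells of other classes was not tested for this pattern. Some genes without a copy, such as Cxcr2 and Adam8, were near level in mature neutrophils, at 0.065 and -0.091. They stood at 1.959 and 3.066 in plasmacytoid dendritic cells, where mixed cells made 2.96% and 14.8%. Others without a copy, such as Snhg9 at 0.992, were higher in mature neutrophils too. The genes without a copy stay open.

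For the third pattern, the interferon list lower in 9 of 10 classes of the library labelled KO, the test of depth over all cells was chosen before its result was seen and the others after. Over all cells the median was -0.260 after thinning and -0.255 before, so it did not rest on the weight of deep cells. This cannot exclude depth, since thinning keeps each gene's expected share of a cell's UMIs. Depth was not excluded within classes either, where 6 of the 9 measured were below 0 after thinning. The lower bound of 29.9% takes classes as independent, which they are not. T cells turned to 0.153 and immature neutrophils had been above 0 before. A different mix of clusters cannot alone account for the lower list, since 23 of 27 clusters had a median below 0. The lower bound of 66.3% takes clusters as independent, which they are not, since all come from the same libraries. Some of these medians rest on few genes, such as 6 in cluster 26. A different mix of cells within a cluster was not tested for this list. RNA from other cells stays open, since the median over every barcode, -0.275, restates that over all cells, and free RNA can carry a difference from some cells into others. The median share per cell of 5 neutrophil genes was higher in the library labelled WT, at 0.163% and 0.0711% in immature or mature B cells and 0.105% and 0.0400% in T cells. Monocyte and macrophage genes were lower in the library labelled KO there, at -0.58 and -0.78. The classes below 0 are thus not separate observations. An effect of genotype and a difference between animals or in handling stay open, and 1 library per genotype does not separate them.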
